A study of Homo sapiens with 5 samples.

How the data were processed

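DRIP-seq libraries of PC-9 cells were used, 2 labelled control and 2 labelled exp, with 1 input library. Per the labels' protocols, nucleic acids were extracted with SDS and proteinase K, sonicated, precipitated with S9.6 and amplified for a number of PCR cycles that depended on the amount of material. They also describe a synthetic hybrid spike-in and an IgG aliquot, which were not analysed here. The submitters' processing notes name FastQC, cutadapt, Bowtie2, MACS2 and DiffBind and the build GRCh38 (hg38); tool versions and settings are not given in the sources used here.

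The deposited files were 4 peak lists, 1 per DRIP library and not pooled. Per the file headers, each peak has a locus, an assigned gene with Ensembl identifier and type, a location class (promoter, gene body, terminator or intergenic), a width, the direction of the transcript, a GC skew and a fold enrichment over a local Poisson background. The boundaries of the classes and the annotation release are not given in the sources used here. The read counts, per the file headers, are those of the DRIP library and of the input library over each peak, whole numbers without normalization, and each DRIP library was counted only over its own peaks. The fold enrichment is a ratio deposited by the authors for each peak and was used only to describe or rank peaks within a list. The p-value and q-value columns deposited by the authors are described in the headers as a log10 with a further multiplier, but the smallest p value column entry was 3.00 in all 4 lists, so they were read as −log10 with a p threshold of 0.001. The lowest −log10 q values of the deposited lists were 1.01, 0.961, 0.852 and 0.828, and 68.0%, 58.9%, 52.0% and 54.3% of peaks in control 1, control 2, exp 1 and exp 2 had q of 0.01 or less. The GC skew score deposited by the authors was taken as referring to the reference strand, because over 25 regions with peaks assigned to genes of both strands its values correlated at r = 0.850. Headers state that peaks are sorted by fold enrichment, while the peaks run by position. Peaks with 0 counted DRIP reads numbered 28, 18, 21 and 17, and 18.2%, 13.1%, 16.5% and 25.7% of peaks had no more DRIP than input reads, without scaling for depth.

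Library totals were not used here, so depth was estimated from the peak caller's own values. Fold enrichment and p were solved for a whole number of reads at the summit and a local background, under the usual MACS2 formulas, within a tolerance of 0.005 on −log10 p (scaled up for larger values), and 99.9% of peaks in each list had a solution. The lowest background shared by many peaks was 1.24, 1.33, 1.42 and 1.20 reads in control 1, control 2, exp 1 and exp 2. It was divided by the shortest peak (294, 343, 333 and 329 bp), taken as the fragment length, to give a relative depth. This assumes that the caller did not scale the DRIP library to the input. The median summit held 10 reads in every list, which sets the precision of a single peak.

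Groups and replicate numbers came from the sample titles. Single values per library were compared by an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333. Peaks sharing at least 1 bp were merged into regions, and regions and genes were counted by the libraries that held them and compared with the 2 mixed splits. Chance overlap came from 100 circular shifts of 1 list within each chromosome. Intervals of shares are Wilson intervals at 95%, and bootstrap intervals used 2000 draws of regions. The bootstrap intervals therefore leave out variation between libraries. Gene names were matched to the RefSeq table of GRCh38.p14 by symbol or unique synonym: 97.0% of protein-coding and 77.5% of all gene names matched. The 21 gene lists, with 899 genes, were fixed before the data were examined. Control-only members of a list were set against 10000 random lists matched in 10 bins on control peak length, with Benjamini-Hochberg adjustment over the lists. Named genes followed a rule fixed at the same time: the 10 strongest control-only and exp-only protein-coding genes by the lower of the 2 libraries' best −log10 q, the 6 strongest in all 4 libraries, up to 4 control-only or exp-only members per list, and FANCI. ANO2, FAM230F and the ribosomal, telomeric and intergenic regions were chosen after their values were seen. Some genes that the rule takes are not reported here.

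The planned design had assumed lists without read counts. Since the lists hold counts, a test was added after seeing the data: edgeR's quasi-likelihood test on DRIP counts of the 1370 regions with exactly 1 peak in each library, with the width of each library's peak as an offset and TMM factors from width-scaled counts. A first version took the factors from unscaled counts. It called 1 region, while on simulated data its unchanged regions were shifted, so the present factors were chosen after both had been seen. Such counts lie over intervals that each library chose itself and only where all 4 libraries had a call. On simulated counts for these regions with 200 changed ones, the test called 68% of 2-fold and 98% of 4-fold changes and 2 of 1170 unchanged regions. Every simulated region had the same dispersion of 0.0214, so these rates may not hold for regions that vary more between libraries. The simulated counts were also drawn in proportion to peak width, which is what the present offset and factors assume. The simulation therefore favours the present version over the first and does not show that real counts follow width. Merging was tested on 2000 simulated regions, whose libraries were all recovered. Peaks of a simulated region always overlapped and neighbouring regions never touched, so this checks the code and not merges of close peaks in the real lists. The list test, on 200 simulated lists of 20 genes, called 2.5% of random lists and 74% of lists with a simulated loss of 60%, before adjustment; the 19 tested lists had 2 to 19 members with a peak in both controls, so this power does not carry over to the small ones.

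Alternatives were stricter and looser q, an equal number of peaks, leaving out each replicate, a 50% overlap, genes overlapped by the peak, a replicate block, and nuclear chromosomes alone. Those added after seeing the data were −log10 q of at least 2, peaks with more DRIP than input reads, the alternatives of the count test, a test of lists against genes of like length and the repeats for GC skew and named genes. GC content and the planned central 500 bp need a genome sequence and were not run. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.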

Results

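RNA:DNA hybrids were mapped by DRIP-seq in PC-9, an established human lung adenocarcinoma cell line. In this assay the S9.6 antibody, which binds RNA:DNA hybrids, pulls down sonicated genomic DNA that carries R-loops, the structures in which a transcript pairs with its template strand. The design compared 2 control libraries with 2 libraries labelled exp, taken here as the knockdown of FANCI that the design text names; FANCI is a Fanconi anaemia protein that acts with FANCD2 in the repair of DNA interstrand crosslinks. A single input library, made without S9.6, entered the present comparisons only as read counts over the peaks. The peak caller's settings are not given in the sources used here, so the deposited peaks and fold enrichments may depend on this library too. The deposited peak lists of the 4 DRIP libraries held 25281 and 23903 peaks in the controls and 16785 and 14354 peaks in the exp libraries. The DRIP reads over these peaks numbered 1266127 in control 1, 1001453 in control 2, 801196 in exp 1 and 646455 in exp 2, with medians of 30, 27, 28 and 24 reads per peak. These sums moved with the length that was called, and whole-library read totals were not used here. The labels do not say whether libraries of 1 group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No RNA measurement was analysed here, so the level of FANCI in the exp cells was not checked.

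FANCI (ENSG00000140525, chromosome 15, GRCh38) held gene-body peaks in 3 libraries. Control 1 had 1 peak at 89257876 to 89258193 with 26 DRIP and 2 input reads. Control 2 had 5 peaks between 89265919 and 89313111 with 19 to 36 DRIP reads each. Exp 1 had 1 peak at 89265837 to 89266338 with 24 DRIP and 4 input reads, overlapping the first of control 2, and exp 2 had no peak assigned to the gene. Peaks at the gene do not measure its expression and so do not check the labels.

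The first comparison asked whether the extent of R-loop signal differed between the groups. The exp libraries held fewer peaks, 15570 ± 1719 (SD, n = 2) against 24592 ± 974 (SD, n = 2) in the controls, a ratio of 0.633. The bases under peaks came to 12.6 ± 0.229 Mb (SD, n = 2) in exp and 19.0 ± 2.14 Mb (SD, n = 2) in control, a ratio of 0.665. The median peak was 481 and 491 bp wide in the exp libraries and 463 and 494 bp wide in the controls. Both exp libraries lay below both controls in peak number and in covered length, and the exact two-sided permutation test gave p = 0.333 for each, the smallest p that 2 libraries against 2 can give. The depth estimated from the peak caller's background was 1.00 in control 1, set as the reference, 0.920 in control 2, 1.01 in exp 1 and 0.866 in exp 2. Genes with at least 1 assigned peak numbered 7047 and 7007 in the controls and 5056 and 4034 in the exp libraries.

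**Figure D1:**
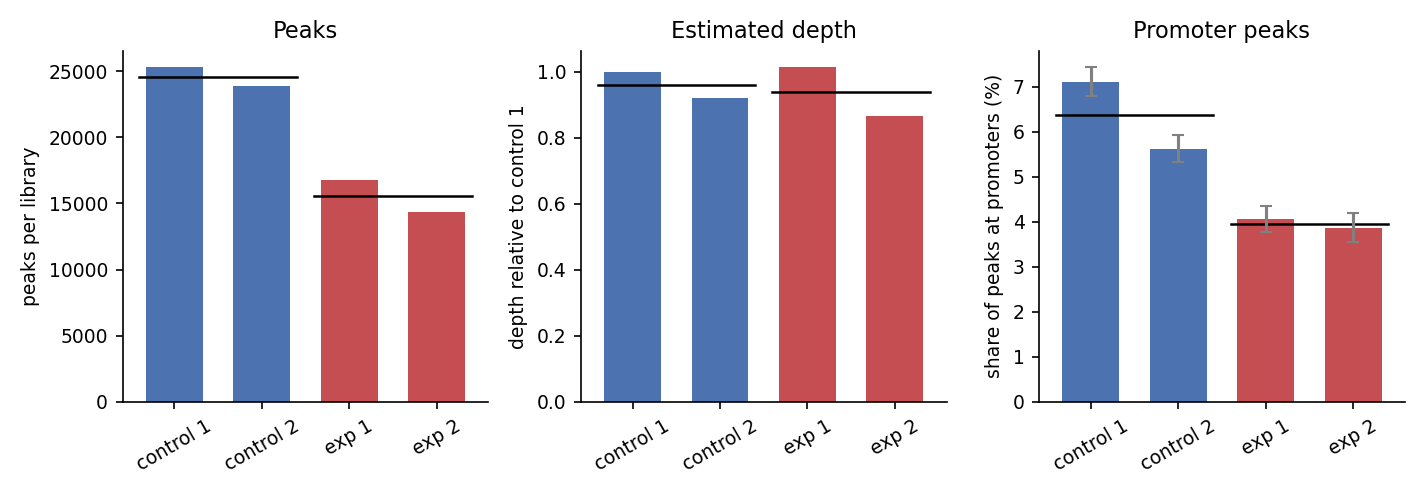
Bars give each library's number of peaks, its depth relative to control 1 as estimated from the background coverage, and its share of peaks at promoters in percent, with 95% Wilson intervals; black lines are group means of 2 libraries. The exp libraries held 16785 and 14354 peaks against 25281 and 23903 in the controls, at estimated depths of 1.01 and 0.866 against 1.00 and 0.920, and 4.05% and 3.86% of their peaks lay at promoters against 7.10% and 5.62%.

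As a ratio of peak numbers, exp over control, the difference was largest at promoters. Promoter peaks numbered 1796 in control 1, 1344 in control 2, 680 in exp 1 and 554 in exp 2, so that exp held 0.393 times as many as control. The corresponding ratio was 0.492 for terminators, 0.579 for peaks in gene bodies alone and 0.708 for intergenic peaks. As a share of all peaks, promoters took 7.10% in control 1 (95% Wilson interval 6.79 to 7.43), 5.62% in control 2 (5.34 to 5.92), 4.05% in exp 1 (3.76 to 4.36) and 3.86% in exp 2 (3.56 to 4.19). Group means were 6.36% ± 1.05 (SD, n = 2) and 3.96% ± 0.136 (SD, n = 2), with an exact two-sided permutation p = 0.333. With the best 14354 peaks of each library the promoter share was 8.46% and 6.19% in the controls against 4.24% and 3.86% in exp. Terminators took 4.90% of control and 3.82% of exp peaks on average, and intergenic sequence took 54.2% and 51.7% of the control peaks and 57.2% and 61.7% of the exp peaks. The intervals cover counting error of peaks only, treating the peaks of a library as independent, and leave out variation between libraries. Reads amplified by PCR without molecular identifiers are not independent molecules either.

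**Figure D2:**
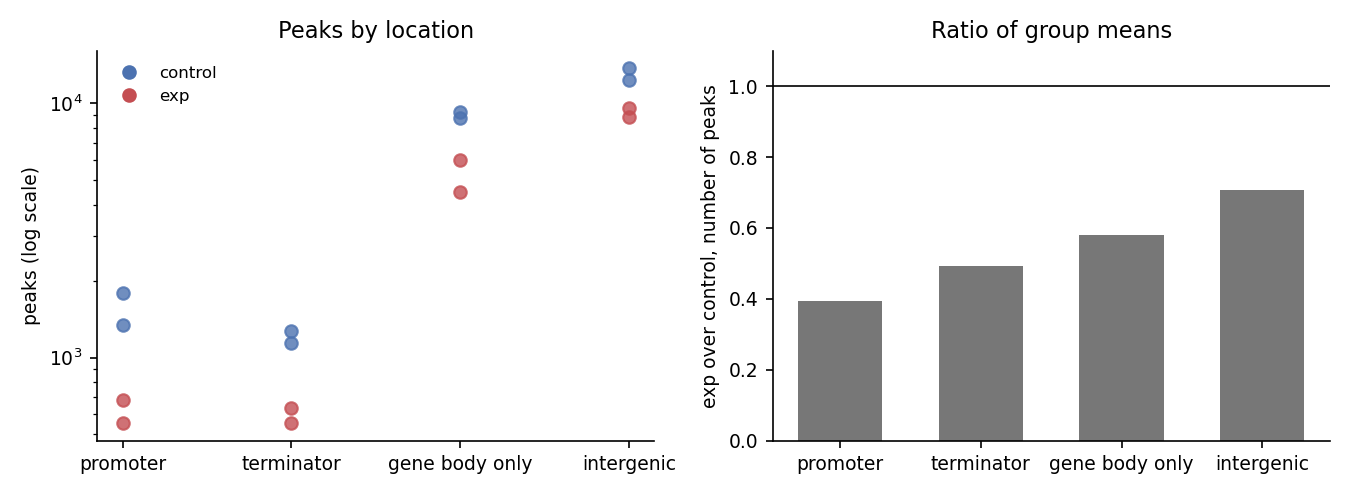
The left panel gives the number of peaks per library on a log scale by location in the transcription unit, with blue points for the 2 control and red points for the 2 exp libraries, and the right panel gives the ratio of the group means, exp over control. The ratio was 0.393 at promoters, 0.492 at terminators, 0.579 in gene bodies alone and 0.708 in intergenic sequence.

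Among regions called in all 4 libraries, the one with the highest −log10 q in its weakest library was intergenic, at chromosome 5, 49656392 to 49661848 (GRCh38), with fold enrichments of 12.7 and 10.2 in the controls and 9.72 and 11.6 in exp. It held 4162 input reads in control 1, where the median peak held 8. Whether this sequence is repeated was not examined, so the position of its reads is uncertain. The 6 strongest genes in all 4 libraries, FP671120.5, FP236383.3, FP671120.7, FP236383.4, FP671120.8 and FP236383.5, lay on the short arm of chromosome 21, beside or over copies of the 45S ribosomal RNA gene. These copies are nearly identical, so the position of reads among them is uncertain. The region at chromosome 21, 8219492 to 8235717 (GRCh38), assigned to FP671120.5, reached fold enrichments of 11.6 and 9.22 in the controls and 8.95 and 9.70 in exp. The peaks at 8209526 to 8211701 over RNA45SN2 and RNA18SN2, assigned to FP671120.7, had fold enrichments of 6.35, 6.51, 6.11 and 6.35 in control 1, control 2, exp 1 and exp 2. The 5S ribosomal RNA array at chromosome 1, 228608460 to 228647041, held a peak over 17, 17, 17 and 16 of its 17 annotated genes in control 1, control 2, exp 1 and exp 2, with fold enrichments of 27.1, 19.8, 17.3 and 16.6. DRIP reads per input read over its peaks were 2.57 and 1.92 in the controls and 1.69 and 1.37 in exp. Over all peaks of each library this ratio had the same order, 2.11 and 1.94 in the controls and 1.85 and 1.39 in exp, without scaling for depth in either case. At the end of the short arm of chromosome 5, 10047 to 11773, the peak had a deposited GC skew of -1, meaning no G on the reference strand, and fold enrichments of 12.2, 10.7, 10.5 and 14.1. Among other non-coding classes, snRNA genes with a peak numbered 22 and 26 in the controls and 13 and 14 in exp, out of 156 annotated. The groups overlapped for tRNA genes, with 17 and 22 of 451 in the controls and 21 and 23 in exp, and for snoRNA genes, with 5 and 7 of 1199 against 7 and 3. Zinc finger genes of the ZNF series with a peak numbered 175 and 183 against 128 and 119, out of 701. All genes with a peak showed the same order, with 7047 and 7007 in the controls and 5056 and 4034 in exp.

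The second comparison asked which regions were called in 1 group only. Merging peaks that shared at least 1 bp gave 58639 regions, of which 45508 (77.6%) were called in a single library and 1859 in all 4. Regions called in both controls and neither exp library numbered 2247, and regions called in both exp libraries and neither control numbered 763. The mixed splits, with 1 control and 1 exp library on each side, gave 1243 against 1071 and 1461 against 1586. When each library was reduced to its best 14354 peaks the counts were 997 control-only and 1012 exp-only regions, and the split of control 1 with exp 2 against control 2 with exp 1 gave 1144 and 1208. An equal peak number itself draws both sides toward balance: the first side held 49.6% of the regions called on 1 side in the real split and 47.4% and 48.6% in the mixed splits. Among peaks with −log10 q of at least 5 there were 233 control-only and 60 exp-only regions. With a library left out, presence in the remaining library of its group suffices: control-only regions then numbered 16890 without control 1 and 17972 without control 2, and exp-only regions 7412 without exp 1 and 9754 without exp 2. Of the control-only regions 8.99% (95% Wilson interval 7.88 to 10.2) included a promoter peak, against 3.01% (2.02 to 4.48) of the exp-only regions and 5.38% (4.44 to 6.50) of those in all 4. For regions called in 1 control and 1 exp library alone, the share was 4.59% for control 1 with exp 1 and 4.52% for control 1 with exp 2. It was 4.98% for control 2 with exp 1 and 2.99% for control 2 with exp 2, the last close to the exp-only share.

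Overlap was measured for every pair of libraries. Averaged over both libraries of a pair, 24.7% of peaks had an overlap for the controls and 25.6% for the exp libraries. Between groups the values were 23.8% for control 1 with exp 1, 28.3% for control 1 with exp 2, 24.7% for control 2 with exp 1 and 25.2% for control 2 with exp 2. By the Jaccard index over bases, the within-group mean of 18.5% exceeded the between-group mean of 17.9% by 0.544 percentage points, less than the SD of 1.34 among between-group pairs. This difference was 2.11 points with peaks of −log10 q of at least 5, 1.30 with −log10 q of at least 2, 0.857 with peaks of more DRIP than input reads and 0.130 at equal peak number. Over the 6 pairs, 18.7% to 23.7% of the peaks of the first library, in the order control 1, control 2, exp 1 and exp 2, overlapped a peak of the other. When the other library's peaks were shifted along their chromosomes this share averaged 1.01% to 1.62% per pair and was at most 2.23% in any shift.

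At gene level, 1050 genes, 774 of them protein-coding, held a peak in both controls and in neither exp library. The reverse held for 169 genes, 113 of them protein-coding, and 1349 genes held a peak in all 4 libraries. The mixed splits gave 449 against 347 and 372 against 649 genes. At equal peak number the real split gave 506 control-only and 323 exp-only genes, and 1 mixed split gave 373 and 546. With a library left out there were 3059 control-only genes without control 1 and 3334 without control 2, and 863 exp-only genes without exp 1 and 1260 without exp 2. In 404 of the 1050 control-only genes (38.5%) and 72 of the 169 exp-only genes (42.6%) the peaks of both libraries fell in 1 region, and in the others they lay at different places in the gene. Genes with a promoter peak in both controls and neither exp library numbered 220, against 22 in the reverse direction. The mixed splits gave 62 against 38 and 74 against 70 genes with a promoter peak. With the best 538 genes with a promoter peak of each library, the real split gave 43 and 42. The mixed splits then gave 31 and 28, and 48 and 41. As for regions, an equal number itself draws both sides toward balance, so this does not show that the difference vanished.

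**Figure D3:**
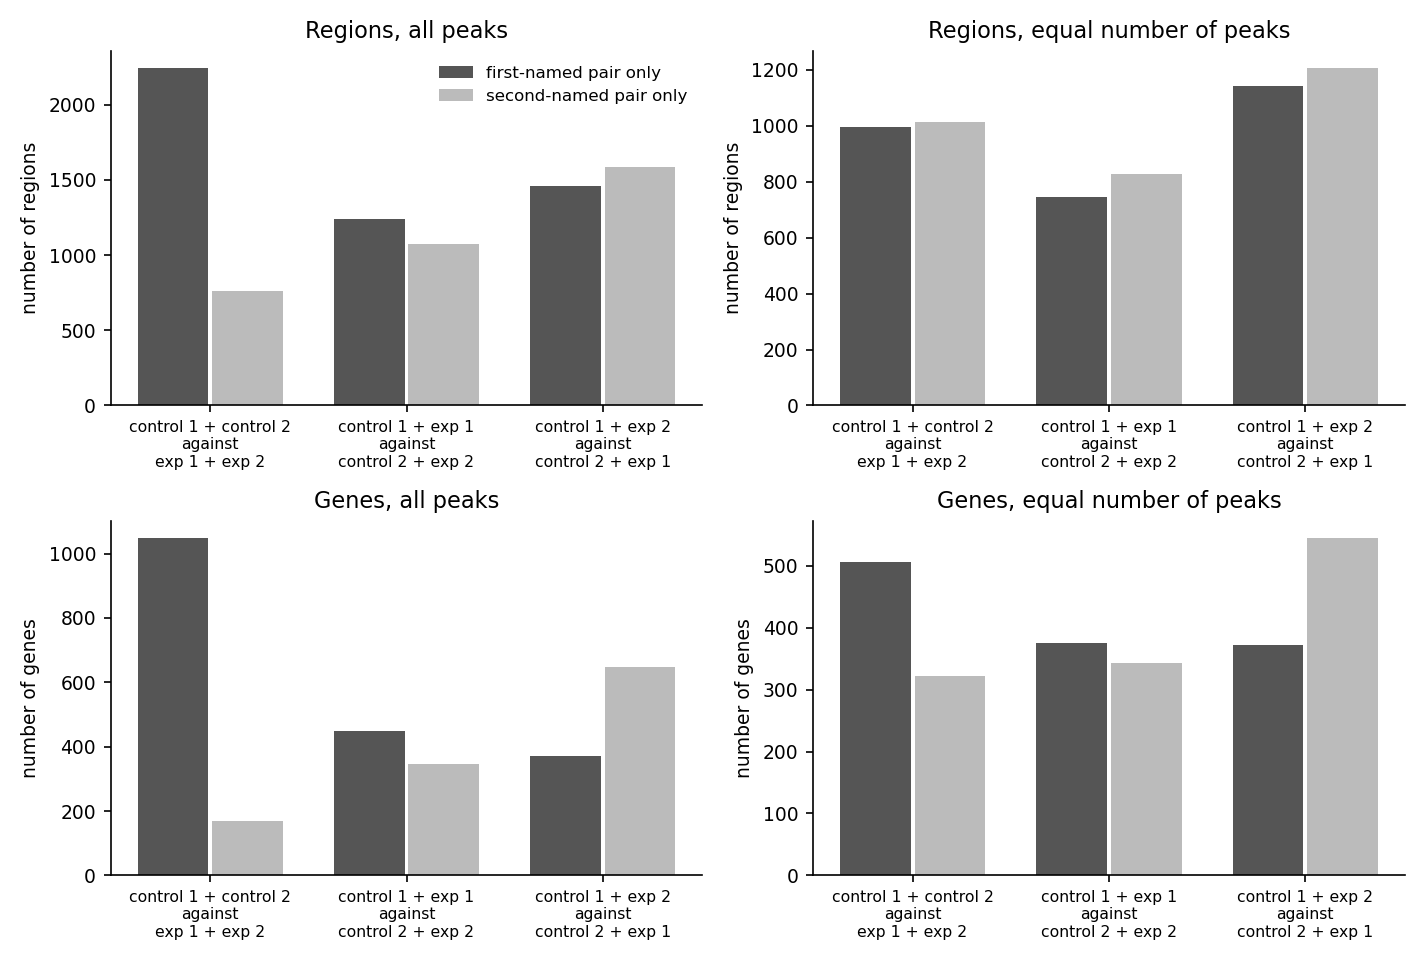
Bars count regions (top) and genes (bottom) called in both libraries of 1 pair and neither library of the other, for the real split of control against exp and for the 2 mixed splits, with all peaks (left) and with the best 14354 peaks of each library (right). With all peaks the real split gave 2247 control-only and 763 exp-only regions, and at equal number 997 and 1012, fewer than the 1144 and 1208 of 1 mixed split.

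Among the strongest control-only protein-coding genes were ITGA7, ZNF488, NRSN2, DENND1B, DHX34, LCK, C17orf67, EEF1A2 and AACS. ITGA7, which encodes a laminin-binding integrin chain, held gene-body peaks at chromosome 12, 55691164 to 55691465, in control 1 (39 DRIP and 7 input reads, fold enrichment 7.79) and at 55690761 to 55691396 in control 2 (36 and 8 reads, fold enrichment 5.97). EEF1A2, a translation elongation factor, held a gene-body peak at chromosome 20, 63491522 to 63493086, with 163 DRIP and 29 input reads in control 1, and one at 63491662 to 63492964 with 93 and 22 reads in control 2. LCK, a kinase of T-cell receptor signalling, held promoter peaks starting at chromosome 1, 32272324, in control 1 (87 DRIP reads) and 32272484 in control 2 (23 DRIP reads). ZNF488 held promoter peaks of fold enrichment 5.74 and 5.17. The peaks of the 2 controls overlapped in ITGA7, ZNF488, NRSN2, LCK, C17orf67 and EEF1A2, and not in DENND1B, DHX34 and AACS.

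The strongest exp-only protein-coding genes by the files' gene types were ZNF70, HNRNPA1P48, HSF5, GPR42, DMBT1, LUZP4, ZNF280B, ZFAND4, PHF19 and VIM. VIM, which encodes the mesenchymal intermediate filament vimentin, held a gene-body peak at chromosome 10, 17229410 to 17229945, in exp 1 (40 DRIP and 3 input reads, fold enrichment 4.55) and at 17229407 to 17229943 in exp 2 (44 and 3 reads, fold enrichment 5.01). HSF5, a member of the heat shock factor family, held a gene-body peak at chromosome 17, 58447990 to 58448431, with 39 DRIP reads in exp 1 and 27 at the overlapping peak of exp 2. PHF19, a Polycomb-associated protein, held peaks of 30 DRIP reads in each exp library. The peaks of both exp libraries overlapped in 9 of these 10 genes, all except ZNF280B. GPR42 has a near-identical paralog, FFAR3, and HNRNPA1P48 resembles HNRNPA1 closely, so both are uncertain. With genes taken by RefSeq overlap, ZNF70, GPR42 and LUZP4 lost the exp-only class, and LCK and DHX34 the control-only class. None of these 10 exp-only genes reached −log10 q of 5 in both exp libraries, while the control-only genes from ITGA7 to AACS did so in both controls. Both sets were ranked by this same value, from 774 control-only and 113 exp-only protein-coding genes. Higher values in the control-only set can therefore follow from the larger pool alone. The named genes were called by presence in a list and had no test of their own, since each library was counted only over its own peaks.

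Gene groups fixed before the data were examined held fewer members with a peak in each exp library than in each control for 13 of 21 lists, an order that 1 of 6 arrangements of the libraries gives, and for no list the reverse. All genes together showed this order too, with 7047 and 7007 holding a peak in the controls and 5056 and 4034 in exp. The lists share the same 4 libraries, so the 13 lists are not independent results. Among 35 genes of the Fanconi anaemia and crosslink repair list, 6 and 9 held a peak in the controls and 5 and 2 in exp. Of the 3 with a peak in both controls, only ERCC1, the partner of the XPF nuclease, had none in exp. Of 49 genes for R-loop regulators, 5 and 10 held a peak in the controls and 4 and 6 in exp, and none of the 3 with a peak in both controls was control-only. For 52 genes of homologous recombination and the damage response the numbers were 13 and 27 against 13 and 12, and DNA2 and TP53BP1 were control-only. For 55 cell cycle genes they were 11 and 11 against 9 and 11, with 0 of 5 control-only. For 54 lung adenocarcinoma drivers they were 16 and 21 against 14 and 10, with ROS1 control-only.

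Epithelial-mesenchymal and adhesion genes held peaks at 17 and 18 of 55 members in the controls and at 9 and 6 in exp. CLDN4, an epithelial claudin, COL4A2 and ITGA2 were control-only, while VIM was exp-only. For 50 genes of Wnt, Notch and Hippo signalling the numbers were 21 and 22 against 16 and 7, and TEAD2, TEAD3, MAML1 and STK4 were among 5 control-only members. For 35 p53 targets they were 9 and 11 against 4 and 2, with BBC3, which encodes the pro-apoptotic protein PUMA, and SERTAD1 control-only. For 40 immediate early and stress genes they were 12 and 10 against 8 and 5, with ZFP36, EGR1 and DDIT4 control-only. For 34 genes of lung epithelial lineages they were 9 and 9 against 6 and 7, with AGER, SCGB1A1 and TP63 control-only and ETV5 exp-only. For 75 ribosomal proteins they were 8 and 14 against 2 and 4, with RPS14 control-only and RPS23 exp-only. For 53 splicing and mRNA processing genes they were 7 and 15 against 14 and 5, with CSTF1 exp-only. For 48 genes of oxidative phosphorylation they were 7 and 4 against 8 and 4, with NDUFS4 exp-only. For 38 interferon and innate sensing genes they were 7 and 9 against 5 and 4, and for 55 replication-dependent histones 3 and 0 against 0 and 1.

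Common fragile site genes, which are very long, held a peak in 24 and 20 of 36 members in the controls and 23 and 15 in exp, with NAALADL2 and DAB1 control-only. Among 23 loci often used as positive loci in DRIP-qPCR, 8 and 10 held a peak in the controls and 4 and 4 in exp, and TFPT, FBXL17, MALAT1 and APOE were control-only. Among 6 loci used as negative ones, 2 and 1 held a peak in the controls and 0 in either exp library, with EGR1 control-only. For both sets of loci any peak assigned to the gene was counted, and the positions of qPCR amplicons were not examined. Genes of other cell types held peaks as well, in 20 and 24 of 38 neuronal genes in the controls against 17 and 16 in exp, with GAD1 and GRIN2B control-only. They did so in 9 and 9 of 39 leukocyte and fibroblast genes against 5 and 4, and in 2 and 3 of 49 olfactory receptors against 3 and 1, with OR4D1 control-only. Of the genes named from the lists, ROS1, VIM, RPS23, RPS14, CSTF1, TEAD3, ZFP36, DDIT4, TFPT and GAD1 had overlapping peaks in both libraries of the group, and the others had peaks at different places in the gene. None of the genes named from the lists kept its class at −log10 q of at least 5. AGER, COL4A2, DAB1, DDIT4, ITGA2, OR4D1, RPS14, SCGB1A1, SERTAD1, TP53BP1 and TP63 lost it both at −log10 q of at least 2 and at equal peak number. ETV5, NDUFS4 and RPS23 lost it in the former setting and not the latter, and NAALADL2 and STK4 the other way round. COL4A2 lost it as well when only peaks with more DRIP than input reads were kept. With genes taken by RefSeq overlap, CLDN4, EGR1, ERCC1, NAALADL2 and ZFP36 also lost it, as did AGER, DAB1, DDIT4, OR4D1, RPS14, SCGB1A1 and SERTAD1.

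Of 3678 gene symbols with a peak in both controls, 28.5% had none in exp, and 0 of 19 lists with at least 2 such members differed from 10000 random lists matched on control peak length (smallest raw two-sided permutation p = 0.210, adjusted p = 1.0 in all 19). The histones and the negative DRIP-qPCR loci had too few members for the test. For 8 of the 19 lists, the Fanconi, R-loop regulator, cell cycle, ribosomal protein, p53, oxidative phosphorylation, positive DRIP-qPCR and olfactory ones, even a control-only class in all members with a peak in both controls could not have passed on its own.

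**Figure D4:**
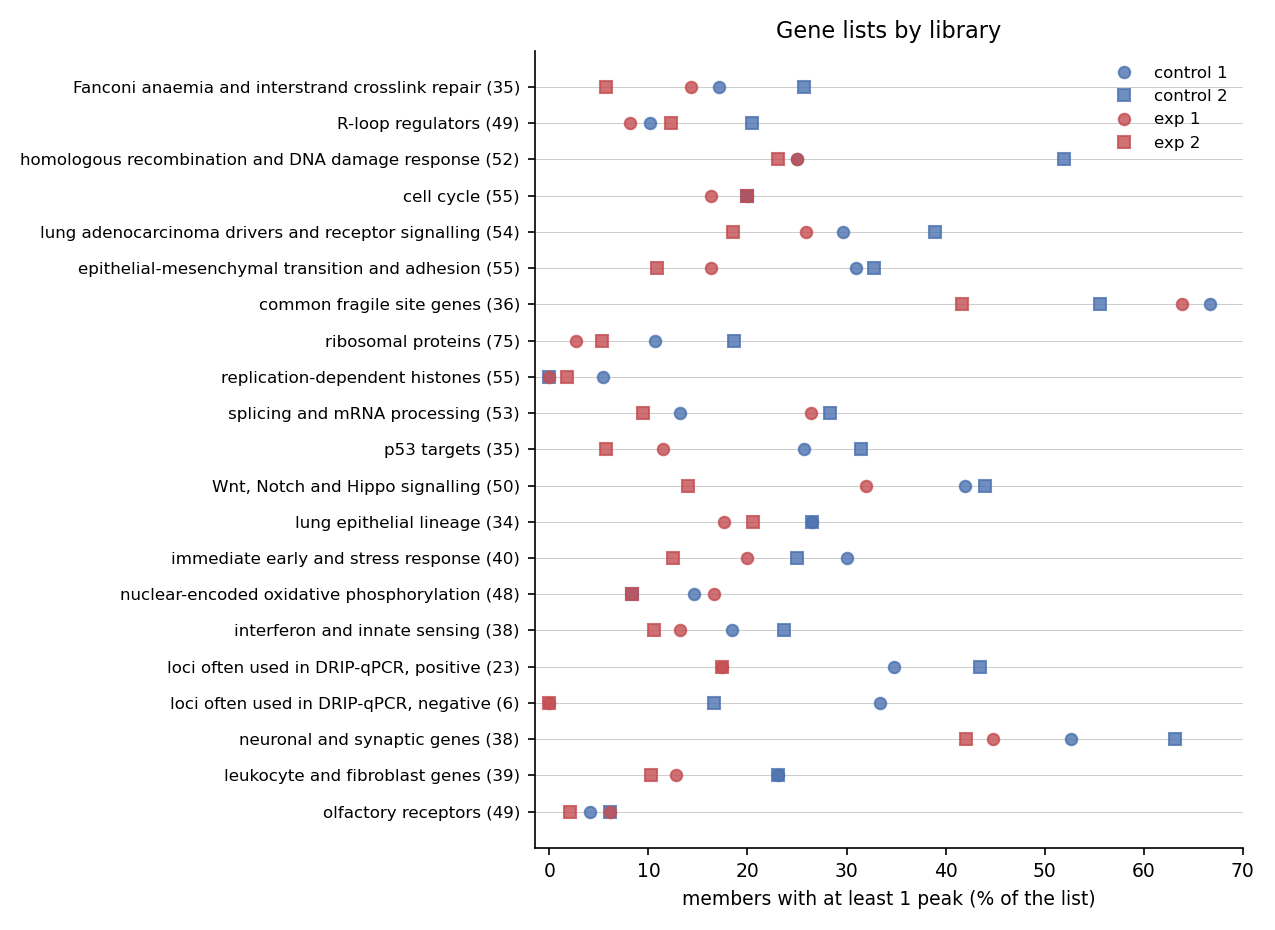
Points give the percentage of each gene list with at least 1 assigned peak in control 1 and control 2 (blue) and exp 1 and exp 2 (red), with the number of list members in parentheses. Common fragile site genes (24, 20, 23 and 15 of 36) and neuronal genes (20, 24, 17 and 16 of 38) held peaks most often.

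Read counts were compared where a region had exactly 1 peak in each library. Over these 1370 regions the DRIP reads summed to 305410 and 219846 in the controls and 226745 and 210041 in exp. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 regions at 0.05, with 95 at an unadjusted p under 0.05, and DESeq2 called 0, with 21 unadjusted. The lowest adjusted p by edgeR was 0.0819, shared by 4 regions. The log2 difference, exp minus control, was 1.04 (SE 0.241) in an intergenic region at chromosome 9, 60610905 to 60615744, and 0.83 (SE 0.211) in a gene-body region of ANO2. It was -1.27 (SE 0.325) at the lncRNA gene FAM230F, which belongs to a family of similar copies and is uncertain. It was -1.92 (SE 0.477) in an intergenic region at chromosome 10, 40001391 to 40004635, where control 1 alone stood apart, with 103 DRIP reads against 7 in control 2, 8 in exp 1 and 10 in exp 2. In a neighbouring intergenic region, 39998347 to 40000321, it was 1.65 (SE 0.506, edgeR adjusted p = 0.191). Whether these intergenic regions hold repeated sequence was not examined, so the position of their reads is uncertain as well. Without exp replicate 1, 3 regions were called, all higher in exp, and with scaling factors from counts not scaled by peak width 1 region was called, higher in exp. The median log2 difference of all regions was 0.01, and -0.13 with library sizes from the background coverage. In the main test the scaling factors came from these same regions, so a median near 0 follows from the scaling. The main test could therefore not show a change shared by all regions. With library sizes from the background coverage 0 regions were called as well. In data simulated over the same 1370 regions, 68% of 2-fold and 98% of 4-fold changes were recovered. That simulation gave all regions the same dispersion, so these rates may not carry over to regions that vary more between libraries. It also drew counts in proportion to peak width, as the test assumes. An intergenic region at chromosome 19, 26712377 to 26714712, differed by -2.20 (SE 0.647) and was not called (edgeR adjusted p = 0.166). Of the 1370 regions, the 77 at promoters had a median log2 difference of -0.06 and the 1293 others 0.01.

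GC skew, the excess of G over C along a strand, was taken from the deposited column. The median absolute skew was 0.191 in control 1, 0.118 in control 2, 0.127 in exp 1 and 0.127 in exp 2. It was 0.201 (bootstrap 95% interval 0.185 to 0.214) in control-only regions, 0.134 (0.122 to 0.146) in exp-only regions and 0.226 (0.187 to 0.265) in regions called in all 4. Without control replicate 1 the difference between control-only and exp-only regions was -0.0265, so its direction rested on that library. This difference was 0.0673 with all peaks, 0.161 at equal peak number, 0.111 at −log10 q of at least 5 and 0.0266 at −log10 q of at least 2. Promoter peaks were G-rich on the coding strand in 52.2% (95% Wilson interval 49.9 to 54.5) and 51.5% (48.8 to 54.2) of cases in the controls and in 47.1% (43.3 to 50.8) and 53.6% (49.4 to 57.7) in exp, each interval including an even split. In gene bodies alone the share was 51.1% (50.04 to 52.1) and 46.4% (45.4 to 47.4) in the controls and 45.8% (44.5 to 47.1) and 49.3% (47.8 to 50.8) in exp. At terminators it was 47.1% (44.4 to 49.9) and 49.0% (46.1 to 51.9) in the controls and 44.4% (40.5 to 48.3) and 49.6% (45.5 to 53.8) in exp. GC content was not analysed here.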

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

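The settings with −log10 q of at least 2 and with more DRIP than input reads, all repeats for GC skew and named genes, and the count test were chosen after seeing the data. Exp stayed below control in peak number, covered length and promoter share under every setting run, with ratios of 0.518 to 0.683, 0.581 to 0.971 and 0.553 to 0.729; the exact permutation test used for them cannot pass 0.05 with 2 libraries per group. Counts of regions and genes moved with the peaks kept. At −log10 q of at least 5 there were 233 control-only, 60 exp-only and 318 regions in all 4, 133 control-only and 18 exp-only genes, 10 of the 20 strongest genes kept their class, within-group overlap exceeded between-group overlap by 2.11 points, and the skew difference was 0.111. At equal peak number there were 997 control-only regions, 1214 in all 4, 506 control-only and 323 exp-only genes, and a skew difference of 0.161. At −log10 q of at least 2 there were 1407, 367 and 1003 regions, and a skew difference of 0.0266. With more DRIP than input reads 1201 regions were in all 4. Leaving out 1 library, so that a group rests on the other, gave 3052 to 17972 control-only regions, 1275 to 9754 exp-only regions, 2358 to 2744 regions in all the libraries kept, 1567 to 3334 control-only genes, 432 to 1260 exp-only genes and skew differences of -0.0265 to 0.0811, lowest without control replicate 1; by construction these counts exceed the main ones. The count test called 1 region with scaling factors from unscaled counts and 0 to 3 with a library left out, the lone library then assumed to vary like the others. No gene list passed in the test of control-only members under the settings run. Of all 55 named control-only or exp-only genes, 10 kept their class at −log10 q of at least 5, 39 at 2, 40 at equal peak number, 37 with genes overlapped by the peak and 54 with more DRIP than input reads. The replicate block gave ratios of 0.632, 0.668 and 0.628 for peaks, covered length and promoter share (exact sign-flip p = 0.5, the smallest for 2 pairs) and 0 regions in the count test, and changed no call. The same-numbered libraries share only a number (r of their deviations -0.0681, and -0.129 without the width offset). An equal number of peaks gives no value for peaks per library, and the central 500 bp could not be run. Keeping fewer peaks in the controls than in exp, relative to the full lists, is how the equal number is built, so exp-only genes are more there; the cause of the other moves was not tested. With a median of 10 reads at a summit, a peak missing from a list is not shown to be absent from the cells.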

Other observations

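The tests of depth, enrichment, peak number, gene density, promoter signal and exchanged labels, and the comparison with genes of like length, were chosen after the results were seen. Against random protein-coding genes of like length, and counting each gene once per library with a peak, immediate early and stress response genes held 35 gene-by-library peaks where 15.8 were drawn on average, a ratio of 2.21 (permutation adjusted p = 0.0420 over 21 lists). Neuronal and synaptic genes held 77 against 53.2, a ratio of 1.45 (permutation adjusted p = 0.0462). Of the 23 positive DRIP-qPCR loci, 20 entered this comparison and held 24 against 11.4, a ratio of 2.10 (permutation adjusted p = 0.0504). Olfactory receptors held 9 against 22.2 (ratio 0.406, adjusted p = 0.0766), R-loop regulators 25 against 40.5 (ratio 0.618, adjusted p = 0.201) and common fragile site genes 82 against 74.7 (adjusted p = 0.831). These values describe genes within these libraries and not a difference between groups.

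Peaks were also placed by the number of protein-coding genes in 1-Mb windows. In 492 windows without such a gene the exp libraries held 3574 and 4082 peaks and the controls 5482 and 3864, and in the 1014 windows with most genes they held 7752 and 6061 against 12279 and 12942. The ratio of group means, exp over control, was 0.819 in windows without genes, 0.662 in windows with some and 0.548 in those with most. Windows with most genes took 46.2% and 42.3% of the exp peaks and 48.6% and 54.2% of the control peaks.

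Both exp libraries held fewer peaks than both controls. Lower sequencing depth as the whole explanation is argued against by the estimated depth, which was 0.978 in exp relative to control while the peak number was 0.633, provided that the caller did not scale the DRIP libraries. Weaker enrichment throughout the exp libraries stays open: at regions called in all 4 libraries the median log2 density of DRIP reads per unit of depth differed by -0.13, but relative to control 1 it was -0.28 in control 2, -0.31 in exp 1 and -0.24 in exp 2, so the groups overlapped, and these regions were selected for being called everywhere. An effect of the knockdown stays open as well and was not tested apart from an enrichment difference between the groups.

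The promoter share was lower in both exp libraries. A different number of called peaks as the whole explanation is argued against, because at an equal number the ratio was 0.553. The equal number keeps the strongest peaks, a cut that itself raised the control shares. They went from 7.10% to 8.46% in control 1 and from 5.62% to 6.19% in control 2, against 4.05% to 4.24% in exp 1. Among peaks with −log10 q of at least 5 the ratio was 0.729. A library bias across gene-rich sequence, such as one from GC content, may contribute and was not excluded: intergenic peaks lay in the windows with most genes at 0.844 times the control share, but the groups overlapped. Within windows with most genes the promoter share was still 10.0% in control and 7.19% in exp, and within windows with some genes 3.88% and 2.23%, with no overlap of the groups in either. Lower promoter signal in the exp cells, the biological explanation, stays open as well, since promoter regions called in all 4 libraries differed from other regions by -0.0766 on the log2 scale (bootstrap 95% interval -0.14 to 0.01). That interval covers the spread over regions and not between libraries. Promoters without a call in some library could not enter this comparison.

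At equal peak number the split of control 1 with exp 2 against control 2 with exp 1 held 2352 regions called on 1 side only, more than the 2009 of the real split and the 1576 of the remaining one. Labels exchanged between 1 control and 1 exp library could give this and stay open: the deviations of same-numbered libraries in read density at shared regions, which an exchange would oppose, had r = -0.0681, or -0.129 without the offset for peak width. In the count test that split called 4 regions, 87 at an unadjusted p under 0.05, against 0 and 95 for the real split by edgeR and 0 and 52 for the remaining one. Peak number and promoter share followed the labels instead. No biological explanation was tested for this pattern.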
